A study of Mus musculus with 12 samples.

How the data were processed

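Per the labels, ribosomal RNA was removed with RNase H, libraries were made with random hexamers, and paired-end reads of 150 bases were sequenced on a NovaSeq. The labels name BV2 cells as the source, while their treatment protocol describes dissected mouse retinas and sorted GFP-positive cells, and the source was followed. The 12 libraries are 3 each of normal glucose, normal glucose with CD200Fc, high glucose, and high glucose with CD200Fc. The deposited table of the authors gives raw counts per gene for each library, with no normalization. The submitters' processing notes name bcl2fastq, STAR, Subread featureCounts, Salmon, edgeR and limma with build GRCm38. They state neither the annotation release nor whether counting was strand-specific, so counts of overlapping genes are uncertain. A second deposited table of the authors gives log2 fold changes with p-values (p_value and false discovery rate) for 4 comparisons. It was used only for the comparison with its calls, for which HG+CD200Fc vs NG was also tested with the model below.

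The count table had 55774 lines for 55487 distinct gene IDs, and 287 repeated lines with identical counts were dropped. Of the IDs 99.5% had an entry in GENCODE M21 (GRCm38), which gave coordinates, exon lengths and GC content. Symbols and biotypes were those of the deposited counts, and 35 listed names were matched by their GENCODE M21 symbol. All per-sample columns were used. Totals per library were 2.15e+07 to 3.19e+07 counts. Reads carry no molecular identifiers, so totals describe counting error only, and the spread between libraries was estimated from the replicates.

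Genes were filtered with filterByExpr on the 4 groups, which left 19182, and libraries were scaled by TMM. One quasi-likelihood model of the 4 group means was fitted to all 12 libraries with edgeR 4.0.16 (robust, R 4.3.3), with a biological coefficient of variation of 0.0908. The contrasts were 5: HG vs NG, HG+CD200Fc vs NG+CD200Fc, NG+CD200Fc vs NG, HG+CD200Fc vs HG, and their interaction. Benjamini-Hochberg adjustment was done within each contrast, and a gene passed at an adjusted p under 0.05. Fold changes are log2, their errors are standard errors from the model, and expression is given in CPM (counts scaled by library total after TMM) as mean ± SD of 3 libraries.

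Gene lists numbered 47 and held 1195 names, of which 1193 were matched to a gene ID. They cover glucose and energy metabolism, lipids, inflammation, interferon, antigen presentation, complement, Fc receptors, CD200 signalling, microglial states, stress responses, proliferation, ribosomes, angiogenesis, adhesion, RNA quality and markers of other cell types. Some genes are in more than 1 list. Each list with at least 5 tested genes (44 lists) was tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over these lists within each contrast. Camera with an estimated correlation and fry were the alternatives. Fry tests whether the genes of a list move 1 way and does not compare them with other genes.

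Genes were named by a rule: for each contrast the 10 highest and 10 lowest fold changes among genes that passed, with a mean of at least 1 CPM and with the 3 libraries of each group not overlapping (not required for the interaction), leaving out predicted genes and pseudogenes. With fewer than 5 such genes, the 5 with the smallest p were named. In each list up to 4 members with the smallest p were eligible, and *Cd200r1*, *Cd200* and *Txnip* in each contrast. The text prints part of these genes. The groups, contrasts, tests, gene lists, naming rule and alternatives were fixed before the data were examined, except where the closing section says otherwise.

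Correlations of fold changes were computed across genes for 2 pairs of contrasts that share no library, and tested two-sided by permuting libraries within each glucose or CD200Fc level (400 relabellings, smallest possible p 0.01). The count of genes passing in opposite directions in HG vs NG and HG+CD200Fc vs HG was set beside 40 simulations of unchanged groups and beside the overlap of independent lists. Each comparison was repeated on other splits of its libraries.

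The test was tested on simulated data in which genes were changed 1.25-fold, 1.5-fold or 2-fold. The changed genes had a mean of at least 1 CPM, so the shares recovered do not cover genes under this level. In HG vs NG it recovered 34.3%, 61.2% and 89.4% of them, with 11 false calls among 18710 genes. For the interaction it recovered 5.97%, 43.3% and 68.2%, with 4 false calls among 18702 genes. A list raised 1.2-fold was recovered, and 0 of 42 other lists were called by camera. Counts were simulated independently for each gene, so this cannot show how often camera wrongly calls a list of correlated genes.

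Alternatives were: DESeq2 size factors or upper quartile scaling, no filter (at least 1 count), a stricter filter (1 CPM and 10 counts in 3 libraries), DESeq2 1.42.0, limma voom with quality weights, a model of only the groups compared, the replicate number as a block, and leaving out each library in turn. The model of only the groups compared and the leave-outs also repeated the gene filter and the scaling on their own libraries, and DESeq2 used its own size factors. An alternative that removed a trend on exon length and GC content (loess, span 0.3) from each library was chosen after seeing the data. No library was left out of the results reported.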

Results

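By their source labels, RNA sequencing libraries were made from BV2 cells, an immortalised mouse microglial line, grown in normal glucose medium (NG) or high glucose medium (HG), each with or without CD200Fc at 50 ng/mL. CD200Fc is a fusion of the ligand CD200 with an antibody Fc part and binds the inhibitory receptor CD200R1 of myeloid cells. The 4 groups, NG, NG+CD200Fc, HG and HG+CD200Fc, held 3 libraries each. The glucose concentrations and the length of treatment are not given in the sources used here, and none of the 4 groups was an Fc or an osmotic control. Total counts per library ran from 2.15e+07 to 3.19e+07. Nothing states that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The labels conflict on the origin of the cells: the source is given as BV2, but the treatment protocol describes retinas taken from mice and sorting of GFP-positive cells. The libraries were taken as BV2 cells, which was not tested. Coordinates are on GRCm38.

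Replicate libraries differed by more than sampling noise, with a chi-square per degree of freedom of 3.74 or more in each pair within a group, and all 12 were kept. On the 1000 most variable genes the first principal component held 19.4% of the variance and the second 12.5%. HG and HG+CD200Fc libraries lay on the positive side of the first component and NG and NG+CD200Fc libraries on the negative side. HG replicate 2 stood apart in composition, with 1.49% of its counts in ribosomal RNA genes against at most 0.119% in the other libraries, and 90.6% in protein-coding genes against at least 91.6%.

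**Figure D1:**
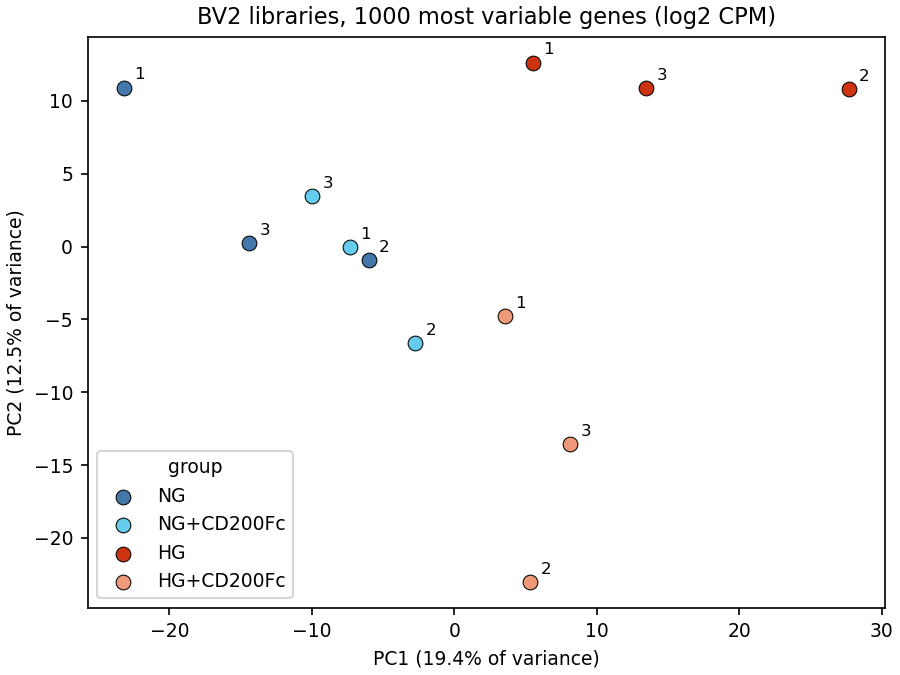
Principal components of the 12 libraries on log2 CPM (counts scaled by library total) of the 1000 most variable genes, first component (19.4% of variance) on the x axis and second (12.5%) on the y axis, points coloured by group and numbered by replicate. The 3 HG libraries have second-component scores of 10.8 to 12.6 and the 3 HG+CD200Fc libraries scores of -23.0 to -4.76.

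The receptor and ligand of the treatment were looked at first. *Cd200r1*, the CD200 receptor gene (ENSMUSG00000022667, chromosome 16, 44765736 to 44794978, plus strand), was expressed at 13.8 ± 1.12 CPM (mean ± SD, n = 3) in NG, 14.4 ± 2.94 in NG+CD200Fc, 13.04 ± 1.01 in HG and 11.9 ± 1.21 in HG+CD200Fc. It passed the test in none of the 4 pairwise comparisons nor in the interaction (edgeR quasi-likelihood, smallest adjusted p = 0.194). The ligand gene *Cd200* had 0 reads in all 12 libraries and *Cd200r3* had 42 in all. *Txnip*, which encodes a glucose-induced regulator of glucose uptake (ENSMUSG00000038393, chromosome 3, 96557957 to 96561883, plus strand), stood at 102 ± 8.09 CPM in NG and 183 ± 8.39 in HG, a log2 fold change of 0.84 ± 0.062 (SE; adjusted p = 1.10e-10).

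The first comparison, HG vs NG, asks what high glucose changed without CD200Fc. Interferon-stimulated, antigen presentation and complement genes were higher in HG, while genes of cell division, ribosome assembly and replication-dependent histones were lower (the histone list not passing with an estimated correlation, camera adjusted p = 0.166). *Irf7*, a transcription factor of the interferon response (ENSMUSG00000025498, chromosome 7, 141262706 to 141266481, minus strand), rose from 73.5 ± 3.05 to 166 ± 9.02 CPM, a log2 fold change of 1.18 ± 0.063. *Cd74*, the invariant chain of MHC class II (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652, plus strand), rose from 18.8 ± 1.24 to 53.8 ± 3.58 CPM (1.52 ± 0.083), and complement component *C3* (ENSMUSG00000024164, chromosome 17, 57203970 to 57228136, minus strand) from 219 ± 13.1 to 414 ± 5.40 CPM (0.92 ± 0.052). Of 19182 genes tested, 4720 passed an adjusted p of 0.05, 2244 higher and 2476 lower. The larger side was not stable, with 47.5% higher here, 53.9% with upper quartile scaling and 50.4% with the stricter filter. At least 2-fold, 449 were higher and 62 lower. In each of the 21 alternatives tried the count stayed within 1.5 times of 4720.

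Of the 45 interferon-stimulated genes tested, 41 were higher in HG and 0 lower (42 higher adjusted over the list alone), with a median log2 fold change of 0.82 (camera adjusted p = 2.20e-57). They included *Stat2* (1.23 ± 0.073), *Oasl2* (1.31 ± 0.077) and *Oas3* (0.83 ± 0.055), which act in interferon signalling and antiviral defence. Among 24 antigen presentation genes, 14 were higher and 0 lower (15 and 1 adjusted over the list alone; median 0.45, adjusted p = 1.76e-13). Members included the peptide transporter *Tap1* (0.84 ± 0.075), the MHC class I regulator *Nlrc5* (0.77 ± 0.069) and *H2-K1* (0.49 ± 0.059), whose reads can be shared with related class I genes. The complement list had 10 of 17 genes higher and 0 lower (12 higher adjusted over the list alone; median 0.41, adjusted p = 1.74e-07). Examples are *C1qb* (1.07 ± 0.096), properdin *Cfp* (0.43 ± 0.064) and *Itgam*, a chain of complement receptor CR3 (0.51 ± 0.10). These 3 lists kept their calls with an estimated correlation.

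**Figure D2:**
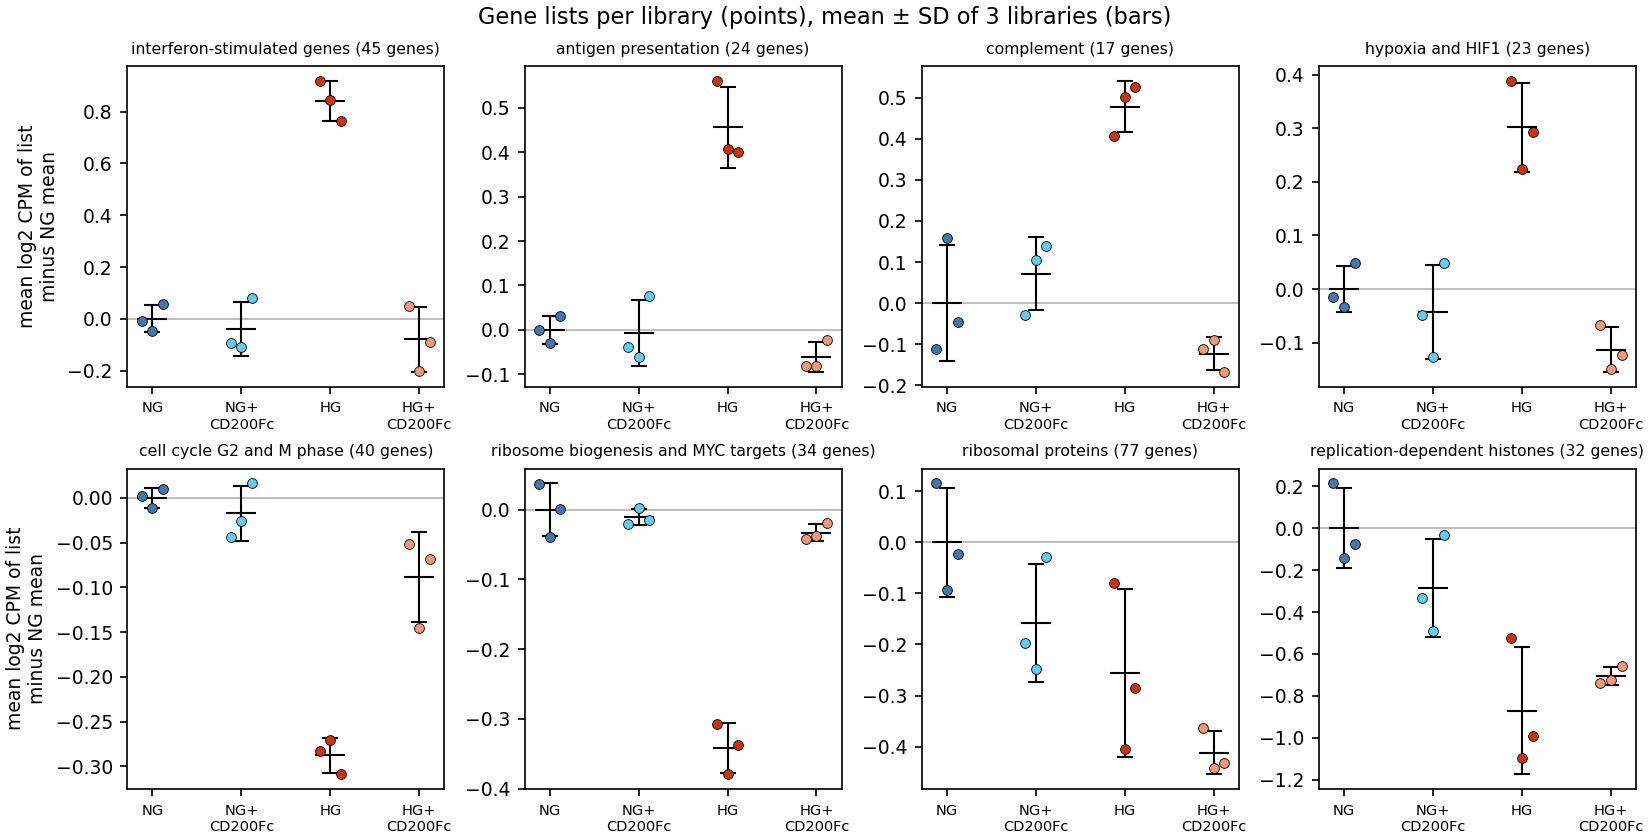
Mean log2 CPM of 8 gene lists in each library (points), as the difference from the NG mean, with bars for the mean ± SD of the 3 libraries of each group. Interferon-stimulated genes lie between 0.76 and 0.92 in the 3 HG libraries and between -0.20 and 0.05 in the 3 HG+CD200Fc libraries. Ribosomal protein genes lie below the NG mean in the libraries of both these groups and of NG+CD200Fc.

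A further 5 immune lists passed as higher, of which only the NF-kB list kept its call with an estimated correlation. Inflammatory cytokines and chemokines did not pass (adjusted p = 0.194). In the NF-kB list 14 of 27 genes were higher and 1 lower (17 and 1 adjusted over the list alone; median 0.20, adjusted p = 2.80e-07), a call kept with an estimated correlation. It was led by the feedback inhibitor *Irak3* (0.73 ± 0.055), *Tnfaip2* (0.64 ± 0.050) and *Irak2* (0.52 ± 0.060). Inflammatory enzymes and inflammasome genes were higher in 9 and lower in 2 of 22 (9 and 2 adjusted over the list alone; median 0.094, adjusted p = 2.33e-06, and adjusted p = 0.0620 with an estimated correlation). Inducible nitric oxide synthase *Nos2* went from 68.3 ± 7.57 to 206 ± 27.4 CPM (1.60 ± 0.10), the gelatinase *Mmp9* (ENSMUSG00000017737, chromosome 2, 164940780 to 164955850, plus strand) from 20.2 ± 1.10 to 59.7 ± 3.82 (1.56 ± 0.079), and *Acod1*, which makes itaconate, from 28.1 ± 0.436 to 79.2 ± 9.34 (1.495 ± 0.093). Toll-like and pattern receptors had 7 of 22 higher and 1 lower (8 and 2 adjusted over the list alone; median 0.15, adjusted p = 0.00265, and adjusted p = 0.136 with an estimated correlation). Genes in this list included the RNA sensors *Ddx58* (0.92 ± 0.076) and *Ifih1* (0.80 ± 0.086). The Fc receptor list had 6 of 10 higher (7 adjusted over the list alone; median 0.38, adjusted p = 9.73e-07, and adjusted p = 0.102 with an estimated correlation). This list held the kinase *Syk* (0.54 ± 0.050) and the receptor *Fcgr4* (0.48 ± 0.067). Alternative activation genes were higher in 6 and lower in 1 of 21 (median 0.23, adjusted p = 0.0152, and adjusted p = 0.136 with an estimated correlation). Among these genes were the interleukin-10 receptor chain *Il10ra* (0.71 ± 0.065) and *Socs3* (0.51 ± 0.085). In HG vs NG the alternative activation list lost its call without NG replicate 2 (median 0.22).

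Glucose-sensing targets rose in 7 of 12 (10 adjusted over the list alone; median 0.29, adjusted p = 3.88e-05), a call kept with an estimated correlation, with the *Txnip* relative *Arrdc4* at 1.11 ± 0.11. Glycolysis and lactate genes were higher in 10 and lower in 1 of 26 (11 and 1 adjusted over the list alone; median 0.12, adjusted p = 4.84e-05, and adjusted p = 0.337 with an estimated correlation). The lactate exporter *Slc16a3* (1.31 ± 0.10) and the enolase *Eno2* (1.18 ± 0.070) rose, whereas the monocarboxylate transporter *Slc16a1* fell (-0.52 ± 0.060). Hypoxia and HIF1 genes were higher in 10 and lower in 1 of 23 (11 and 1 adjusted over the list alone; median 0.18, adjusted p = 1.72e-04, and adjusted p = 0.202 with an estimated correlation). Members included *Ndrg1* (1.27 ± 0.11), the mitophagy receptor *Bnip3* (1.17 ± 0.18) and *Vegfa* (0.51 ± 0.063). Cholesterol efflux and LXR targets had 5 of 12 higher (median 0.16, adjusted p = 4.12e-04, and adjusted p = 0.121 with an estimated correlation). Examples are *Pltp* (0.99 ± 0.067) and the cholesterol exporter *Abca1* (0.58 ± 0.054).

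Genes of proliferation fell. In the G2 and M phase list 34 of 40 were lower and 0 higher (36 lower adjusted over the list alone; median -0.28, adjusted p = 1.03e-16). Genes in this list included cyclin A2 (*Ccna2*, -0.62 ± 0.060) and the mitotic activator *Cdc20* (-0.44 ± 0.060). The S phase list had 26 of 36 lower (29 adjusted over the list alone; median -0.28, adjusted p = 2.74e-12). This list held the replicative helicase subunit *Mcm5* (-0.47 ± 0.055) and *Pcna* (-0.50 ± 0.064). Ribosome biogenesis and MYC targets were lower in 29 of 34 (31 adjusted over the list alone; median -0.36, adjusted p = 1.12e-21). Among these genes were nucleolin (*Ncl*, -0.49 ± 0.050), the pseudouridine synthase *Dkc1* (-0.56 ± 0.056) and spermidine synthase (*Srm*, -0.47 ± 0.056). These 3 lists kept their calls with an estimated correlation.

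Histone, oxidative phosphorylation and ribosomal protein genes were also lower, but none of these 3 lists passed with an estimated correlation. Replication-dependent histones fell in 31 of 32 (32 adjusted over the list alone; median -0.88, adjusted p = 4.53e-23, and adjusted p = 0.166 with an estimated correlation), near-identical copies that can share reads. Nuclear oxidative phosphorylation genes were lower in 41 of 70 (50 adjusted over the list alone; median -0.27, adjusted p = 1.76e-13, and adjusted p = 0.373 with an estimated correlation). Members included the complex I subunit *Ndufa8* (-0.50 ± 0.079). Ribosomal protein genes were lower in 41 of 77 (62 adjusted over the list alone; median -0.27, adjusted p = 6.05e-13, and adjusted p = 0.455 with an estimated correlation). Over 14489 genes of at least 1 CPM the log2 fold change rose with exon length (Spearman rho = 0.184 across genes, which are not independent replicates). The medians of the histone, oxidative phosphorylation and ribosomal protein lists were -0.75, -0.20 and -0.21 with a trend on exon length and GC removed.

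A further 5 lists passed, none of which kept its call with an estimated correlation. NRF2 antioxidant genes were lower in 10 and higher in 3 of 26 (median -0.16, adjusted p = 0.00392, and adjusted p = 0.498 with an estimated correlation). Genes in this list included the glutathione synthesis gene *Gclc* (-0.56 ± 0.060). Heat shock genes were lower in 7 and higher in 1 of 15 (median -0.19, adjusted p = 0.00595, and adjusted p = 0.166 with an estimated correlation). This list held the co-chaperone *Fkbp4* (-0.37 ± 0.058). Citrate cycle genes were lower in 7 of 26 (median -0.10, adjusted p = 0.00646, and adjusted p = 0.537 with an estimated correlation). Integrated stress response and amino acid genes were lower in 12 and higher in 3 of 30 (median -0.12, adjusted p = 0.0357, and adjusted p = 0.498 with an estimated correlation). Among these genes was the amino acid transporter *Slc7a5* (-0.40 ± 0.059). The endothelium and mural cell markers were higher in 3 and lower in 1 of 9 tested (median 0.57, adjusted p = 0.0347, and adjusted p = 0.202 with an estimated correlation). *Vwf* stood at 142 ± 4.94 CPM in NG and 237 ± 1.49 in HG, and *Flt1* at 239.5 ± 11.3 and 162 ± 4.49. In HG vs NG the citrate cycle list lost its call without HG replicate 2 (median -0.082) and the integrated stress response list with upper quartile scaling, with the stricter filter and without NG replicate 3 (-0.13) or HG replicate 2 (-0.084). The endothelium and mural cell list lost its call with the stricter filter, with limma voom, with the exon length and GC trend removed and without NG replicate 1 (0.45) or 2 (0.46), HG replicate 3 (0.43) or HG+CD200Fc replicate 2 or 3 (0.53 in both).

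By the rule for named genes, the largest increases in HG besides *Mir6236* were *Gpr132* (2.23 ± 0.37), the guanylate-binding protein gene *Gbp4* (2.09 ± 0.34), the endocytic receptor *Ly75* (1.99 ± 0.42), *Apol9a* (1.98 ± 0.19), *Crybg2* (1.93 ± 0.30), *Apol9b* (1.89 ± 0.26), the inhibitory receptor *Pirb* (1.86 ± 0.12), *Gbgt1* (1.73 ± 0.20) and *Abcc6* (1.73 ± 0.34). *Apol9a* and *Apol9b* are near-identical neighbours and *Gbp4* has close relatives, so their counts are uncertain. The largest decreases were *Dmpk* (-2.02 ± 0.36), the interleukin-13 decoy receptor *Il13ra2* (-1.89 ± 0.34), *Pmepa1* (-1.85 ± 0.40), *Id1* (-1.51 ± 0.088), *Etv4* (-1.46 ± 0.14), *Hist1h2an* (-1.37 ± 0.21), the fractalkine receptor *Cx3cr1* (-1.36 ± 0.28), *H2ac13* (-1.29 ± 0.19), *Epha2* (-1.21 ± 0.15) and *H4c1* (-1.14 ± 0.26). *Gpr132* moved to 2.96 without NG replicate 2 and *Pmepa1* to -2.45 without HG replicate 2. Of these genes *H4c1* had the largest adjusted p after *Mir6236*, 0.0146, and lost its call without NG replicate 1, HG replicate 2 or HG replicate 3 or with only the groups compared. Its log2 fold change ranged from -1.49 to -0.98 over the alternatives. *Mir6236* had the largest fold change (5.66 ± 1.73, adjusted p = 0.0458), but stood at 1252 CPM (before TMM scaling) in HG replicate 2 against 16.9 and 24.8 in the other HG libraries. Its call was lost in 15 of the 21 alternatives, among them those without NG replicate 1, 2 or 3, NG+CD200Fc replicate 1, 2 or 3, HG replicate 2 or HG+CD200Fc replicate 1, 2 or 3. Its lowest log2 fold change was 1.30.

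The remaining lists did not pass in HG vs NG. Their medians and adjusted p were -0.15 and 0.126 for mitochondrially encoded genes (which passed without NG replicate 2, median -0.18), -0.074 and 0.126 for CD200 receptor signalling, -0.026 and 0.161 for p53 and apoptosis, -0.17 and 0.161 for pentose phosphate, polyol and hexosamine genes, and 0.20 and 0.194 for inflammatory cytokines and chemokines (which passed with the exon length and GC trend removed, median 0.28). They were 0.10 and 0.194 for fatty acid synthesis and lipid storage, -0.0053 and 0.307 for immediate early and AP-1 genes, -0.13 and 0.342 for homeostatic microglia, -0.092 and 0.377 for disease-associated microglia, and 0.019 and 0.377 for the unfolded protein response. Angiogenic factors had a median of -0.042 and a mean of 0.065 (adjusted p = 0.454). Osmotic stress genes had a median of 0.098 and a mean of -0.018 (adjusted p = 0.629), so in both the median and the mean differed in sign. They also differed in sign for p53 and apoptosis (mean 0.028) and cholesterol synthesis (mean 0.020). The median of the phagocytosis list changed sign with DESeq2 size factors, and those of the p53, immediate early and cholesterol synthesis lists with upper quartile scaling. Nuclear noncoding RNA and RNA quality genes (-0.35, adjusted p = 0.582), cholesterol synthesis (-0.015, adjusted p = 0.615), phagocytosis and lysosome (0.0068, adjusted p = 0.669) and migration and adhesion receptors (0.034, adjusted p = 0.870) did not pass either. Within them, the nuclear RNA *Malat1* was higher in HG (0.83 ± 0.057), as were the scavenger receptor *Marco* (1.26 ± 0.057) and the chemokine *Ccl5* (0.81 ± 0.13), while *P2ry6* (-0.65 ± 0.068), *Igf1* (-0.60 ± 0.054) and *Lpl* (-0.53 ± 0.053) were lower. Markers of other cell types had few tested members: lymphocytes 6 (median 0.83, adjusted p = 0.145), astrocytes 6 (0.14, adjusted p = 0.348), granulocytes and mast cells 5 (0.62, adjusted p = 0.528), retina and pigment epithelium 6 (0.14, adjusted p = 0.636) and oligodendrocytes 8 (0.19, adjusted p = 0.870). Neurons (4 tested, median -0.14), epithelium (2 tested, median 0.60) and fibroblasts (1 tested, log2 fold change 0.89) had too few members for a test.

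The second comparison, NG+CD200Fc vs NG, asks what CD200Fc changed in normal glucose. Of the genes higher in HG than in NG, *Irf7* stood at 73.5 ± 3.05 CPM in NG and 70.6 ± 5.88 in NG+CD200Fc (log2 fold change -0.056 ± 0.064). In the same order *Cd74* stood at 18.8 ± 1.24 and 19.1 ± 0.900 (0.025 ± 0.085) and *Txnip* at 102 ± 8.09 and 98.1 ± 3.98 (-0.056 ± 0.062). The 2244 genes higher in HG than in NG had a median log2 fold change of 0.082 with CD200Fc in normal glucose, and the 449 of them at least 2-fold higher a median of 0.31. Both comparisons use the same NG libraries, so chance in these moves both the same way. No gene passed with edgeR, DESeq2 or limma voom (0 each), the smallest adjusted p with edgeR was 0.816, and 1147 genes had an unadjusted p under 0.05 with edgeR. This last count was 684 without NG replicate 1, 2193 without NG+CD200Fc replicate 3 and 2504 with limma voom. The genes with the smallest p, which did not pass, were *Atp5k* (-0.39 ± 0.083), *Mrps21* (-0.31 ± 0.078), *Chrac1* (-0.35 ± 0.087), *Fam71f1* (-3.36 ± 0.87) and *Bcr* (0.35 ± 0.092). Leaving out HG replicate 1 gave 8 calls, with *Atp5k* among them, and leaving out each of the other libraries gave 0. With no filter 21 genes passed (*Atp5k* and *Chrac1* among them), with only the groups compared 9 (*Atp5k* among them) and with the replicate block 2. On counts simulated for this comparison the test recovered 32.8% of genes with the smallest simulated change (median estimated log2 fold change 0.32), 68.7% of those changed 1.5-fold and 80.3% of those changed 2-fold. The changed genes had a mean of at least 1 CPM.

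In NG+CD200Fc vs NG, 5 lists were lower with CD200Fc by camera with a preset correlation: oxidative phosphorylation (median -0.17, adjusted p = 1.06e-21), ribosomal proteins (-0.16, adjusted p = 1.88e-21), histones (-0.30, adjusted p = 2.46e-12), NRF2 antioxidant (-0.085, adjusted p = 0.00352) and disease-associated microglia (-0.060, adjusted p = 0.0418). With an estimated correlation each had an adjusted p = 0.954, and with fry none passed. The number of lists passing was 3 to 9 when each library was left out in turn, 3 without NG replicate 1 and 9 without NG+CD200Fc replicate 3. The NRF2 list lost its call without NG replicate 1 (median -0.043), and the disease-associated microglia list without NG replicate 1 (-0.060), NG+CD200Fc replicate 1 (-0.058) or 2 (-0.049) or HG+CD200Fc replicate 2 or 3 (-0.063 in both). Without NG+CD200Fc replicate 3 the interferon list passed as lower (median -0.096, against -0.019 and adjusted p = 0.506 with all libraries). The log2 fold change rose with exon length across genes in this comparison too (Spearman rho = 0.276). The median, mean or test of the glucose-sensing, cholesterol synthesis, pattern receptor, antigen presentation, migration, oligodendrocyte, granulocyte and retina lists differed in sign, and none of these passed.

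The third comparison, HG+CD200Fc vs HG, asks what CD200Fc changed in high glucose. Interferon-stimulated, antigen presentation, complement and Fc receptor genes were lower with CD200Fc, and ribosome biogenesis genes were higher. *Irf7* fell from 166 ± 9.02 to 73.8 ± 2.24 CPM, a log2 fold change of -1.17 ± 0.063, and *C1qb* (ENSMUSG00000036905, chromosome 4, 136880129 to 136886187, minus strand) from 51.1 ± 4.93 to 20.2 ± 2.43 (-1.33 ± 0.098). *Cad*, the enzyme that starts pyrimidine synthesis (ENSMUSG00000013629, chromosome 5, 31054780 to 31078479, plus strand), rose from 589.7 ± 25.8 to 966 ± 75.2 CPM (0.71 ± 0.061). In all 3408 genes passed (edgeR, adjusted p under 0.05), 1815 higher and 1593 lower (53.3% higher, but 49.5% without HG replicate 2), and at least 2-fold 44 were higher and 220 lower. In each of the 21 alternatives tried the count stayed within 1.5 times of 3408.

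Of 45 interferon-stimulated genes 39 were lower and 0 higher (41 lower adjusted over the list alone; median -0.86, adjusted p = 8.61e-81). Members included *Ifit2* (-1.62 ± 0.11), *Oasl2* (-1.37 ± 0.077) and *Trim30a* (-1.02 ± 0.075). Antigen presentation genes were lower in 18 of 24 (21 lower and 1 higher adjusted over the list alone; median -0.48, adjusted p = 5.93e-20). Examples are *Tap1* (-0.88 ± 0.075), the class I light chain *B2m* (-0.66 ± 0.060) and *Cd74* (-0.81 ± 0.080). Complement genes were lower in 11 of 17 (12 adjusted over the list alone; median -0.62, adjusted p = 3.23e-14). Genes in this list included *C1qc* (-0.92 ± 0.087), *Cfp* (-0.78 ± 0.065) and *C3* (-0.62 ± 0.052). Fc receptor genes were lower in 9 of 10 (9 adjusted over the list alone; median -0.48, adjusted p = 4.08e-14). This list held *Fcgr4* (-0.78 ± 0.067) and the inhibitory receptor *Fcgr2b* (-0.88 ± 0.090). Inflammatory enzymes were lower in 10 of 22 (13 lower and 1 higher adjusted over the list alone; median -0.25, adjusted p = 2.05e-09). Among these genes were *Acod1* (-1.42 ± 0.093), *Mmp9* (-1.17 ± 0.078) and *Nos2* (-1.03 ± 0.10). Toll-like and pattern receptors were lower in 9 and higher in 1 of 22 (the same counts adjusted over the list alone; median -0.32, adjusted p = 5.73e-07). Ribosome biogenesis and MYC targets were higher in 25 of 34 (29 adjusted over the list alone; median 0.32, adjusted p = 1.12e-21). Members included *Mybbp1a* (0.52 ± 0.050), *Srm* (0.54 ± 0.056) and the helicase *Ddx21* (0.45 ± 0.050). These 7 lists kept their calls with an estimated correlation.

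Of the other 16 lists that passed with the preset correlation, glycolysis and lactate genes were lower in 15 and higher in 1 of 26 (median -0.21, adjusted p = 6.72e-10, and adjusted p = 0.147 with an estimated correlation). An example is *Slc16a3* (-1.47 ± 0.10). Hypoxia and HIF1 genes were lower in 11 of 23 (median -0.23, adjusted p = 3.86e-09, and adjusted p = 0.0700 with an estimated correlation). Genes in this list included *Ndrg1* (-1.32 ± 0.11). Cytokines and chemokines were lower in 9 of 19 (median -0.40, adjusted p = 2.77e-05, and adjusted p = 0.0845 with an estimated correlation). This list held *Cxcl2* (-0.71 ± 0.099) and *Ccl7* (-0.75 ± 0.12). Glucose-sensing targets were lower in 5 and higher in 1 of 12 (median -0.13, adjusted p = 0.0106, and adjusted p = 0.0744 with an estimated correlation), and *Txnip* fell to 123 ± 5.90 CPM (-0.57 ± 0.061). The G2 and M phase list had 18 of 40 higher (median 0.18, adjusted p = 5.91e-11, and adjusted p = 0.0700 with an estimated correlation). Among these genes was the mitotic kinase *Plk1* (0.52 ± 0.054). The S phase list had 17 of 36 higher (median 0.19, adjusted p = 2.10e-08, and adjusted p = 0.0801 with an estimated correlation).

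In HG+CD200Fc vs HG ribosomal protein genes were lower in 11 of 77 (median -0.17, adjusted p = 1.34e-05, and adjusted p = 0.710 with an estimated correlation). Oxidative phosphorylation genes were lower in 11 and higher in 1 of 70 (median -0.15, adjusted p = 0.00128, and adjusted p = 0.742 with an estimated correlation). The medians of the other 8 lists were -0.22 for disease-associated microglia, -0.15 for phagocytosis and lysosome, -0.12 for cholesterol efflux, -0.14 for the unfolded protein response, -0.12 for NF-kB, 0.084 for the integrated stress response, 0.072 for heat shock and 0.16 for immediate early genes. Their adjusted p with an estimated correlation lay between 0.140 (cholesterol efflux) and 0.448 (immediate early genes). Without HG replicate 1 the ribosomal protein (median -0.056), oxidative phosphorylation (-0.026), unfolded protein response (-0.082) and NF-kB (-0.081) lists lost their calls. NF-kB lost its call also without HG+CD200Fc replicate 1 (-0.066), the integrated stress response without HG replicate 2 (0.061), and immediate early genes without HG replicate 2 (0.12) or HG+CD200Fc replicate 2 (0.13). Nuclear noncoding RNA and RNA quality genes did not pass (median -0.13, adjusted p = 0.242), but *Malat1* was lower (-0.57 ± 0.057). CD200 receptor signalling genes did not pass as a list (median 0.065, adjusted p = 0.383), with 5 of 10 members higher and 1 lower. The median, mean or test differed in sign for the pentose phosphate, citrate cycle, homeostatic microglia, p53, angiogenic, migration and astrocyte lists, none of which passed. The lower member of the CD200 list, *Cd200r4* (-0.42 ± 0.12, adjusted p = 0.0117), lost its call without HG replicate 1 or HG+CD200Fc replicate 2, with a range of -0.47 to -0.30 over the alternatives.

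The largest decreases with CD200Fc in high glucose were the cytokine gene *Il1a* (-3.07 ± 0.43), *Ankrd37* (-2.21 ± 0.31), *Apol9b* (-2.19 ± 0.27), *Apol9a* (-2.07 ± 0.19), *Abcc6* (-2.03 ± 0.35), *Cd4* (-1.82 ± 0.35), *Gbp4* (-1.75 ± 0.33), *Ly75* (-1.72 ± 0.41), *Bnip3* (-1.71 ± 0.19) and *Mturn* (-1.69 ± 0.31). *Il1a* (ENSMUSG00000027399, chromosome 2, 129299610 to 129309972, minus strand) was low throughout, at 2.63 ± 0.145 CPM in HG and 0.293 ± 0.268 in HG+CD200Fc. Its log2 fold change ranged from -4.17 without HG+CD200Fc replicate 1 to -2.69 without HG+CD200Fc replicate 2. The largest increases were *Dmpk* (ENSMUSG00000030409, chromosome 7, 19083849 to 19093821, plus strand; 2.63 ± 0.36), *Pmepa1* (1.68 ± 0.41), *Cx3cr1* (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879, minus strand; 1.51 ± 0.28), *Epha2* (1.51 ± 0.14), *Ube2cbp* (1.31 ± 0.28), *Tbr1* (1.30 ± 0.34), *Kcna3* (1.15 ± 0.27), *Etv4* (1.13 ± 0.14), *Kcnh2* (1.07 ± 0.33) and *Ccdc88c* (1.03 ± 0.19). *Cx3cr1* stood at 3.38 ± 0.848 CPM in NG, 1.31 ± 0.547 in HG and 3.77 ± 0.465 in HG+CD200Fc. *Pmepa1* moved to 2.27 without HG replicate 2. The largest adjusted p among these genes was 0.0211 (*Kcnh2*), whose call was lost without HG replicate 2 or 3 or HG+CD200Fc replicate 2 (range 0.86 to 1.47 over the alternatives). By the rule for named genes, in each of them the 3 libraries of one group lay above the 3 of the other, which chance gives in 10% of genes.

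The fourth comparison, HG+CD200Fc vs NG+CD200Fc, asks what high glucose changed in the presence of CD200Fc. *Cd74* (0.68 ± 0.083), *Nos2* (0.67 ± 0.10), *Mmp9* (0.42 ± 0.081), *Txnip* (0.33 ± 0.062), *C3* (0.28 ± 0.052) and the NF-kB cofactor *Bcl3* (0.46 ± 0.079) were higher in high glucose. The metalloelastase *Mmp12* (-0.63 ± 0.10), the linker histone *H1f4* (-0.56 ± 0.071), *Lilr4b* (-0.36 ± 0.057), the lysosomal enzyme *Ctsd* (-0.28 ± 0.058) and *Igf1* (-0.30 ± 0.053) were lower. The largest adjusted p of these genes was 0.00450 (*Ctsd*). Interferon-stimulated genes did not pass as a list (median -0.058, adjusted p = 0.549, 1 of 45 higher and 0 lower), nor did antigen presentation genes (median -0.085, adjusted p = 0.389). In all 1593 genes passed, 892 higher and 701 lower (56.0% higher, 69.3% with upper quartile scaling, but 48.2% with no filter or without HG replicate 1 and 49.6% without NG+CD200Fc replicate 2), and at least 2-fold 40 were higher and 15 lower. This count moved more than those above: 277 genes passed without HG+CD200Fc replicate 2, 344 without NG+CD200Fc replicate 3, 646 without HG+CD200Fc replicate 3, 665 without NG+CD200Fc replicate 1, 1012 with the exon length and GC trend removed and 2559 with limma voom.

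Lists lower in HG+CD200Fc than in NG+CD200Fc with the preset correlation were ribosomal proteins (32 of 77, 61 adjusted over the list alone; median -0.29, adjusted p = 7.35e-26), oxidative phosphorylation (24 of 70, 47 adjusted over the list alone; median -0.27, adjusted p = 3.10e-20), histones (median -0.42, adjusted p = 9.80e-14), disease-associated microglia (10 of 26; median -0.20, adjusted p = 1.22e-06) and mitochondrially encoded genes (median -0.29, adjusted p = 9.21e-06). Also lower were phagocytosis and lysosome (median -0.12), S phase (-0.077), G2 and M phase (-0.072), NRF2 antioxidant (-0.084), citrate cycle (-0.089), cholesterol synthesis (-0.12), complement (-0.12) and cytokine (-0.16) genes, with adjusted p between 0.00370 (phagocytosis and lysosome) and 0.0432 (cytokines). NF-kB (0.074, adjusted p = 0.00497), osmotic stress (0.14, adjusted p = 0.0139) and glucose-sensing (0.13, adjusted p = 0.0338) lists were higher. With an estimated correlation 0 of these 16 lists passed (smallest adjusted p = 0.573), and with fry 4 lists passed. In HG+CD200Fc vs NG+CD200Fc, leaving out 1 library ended the calls of 8 lists. These were citrate cycle (median -0.052 without NG+CD200Fc replicate 3), G2 and M phase (-0.051 without HG+CD200Fc replicate 2), osmotic stress (0.13 without NG+CD200Fc replicate 2) and NRF2 (-0.058 without HG+CD200Fc replicate 3). Cholesterol synthesis was lost without NG+CD200Fc replicate 1 (-0.13) or 3 (-0.11) or HG+CD200Fc replicate 3 (-0.10), and complement without NG+CD200Fc replicate 3 (-0.095) or HG+CD200Fc replicate 1 (-0.18) or 3 (-0.19). The glucose-sensing list was lost without NG+CD200Fc replicate 1 (0.072) or 2 (0.14) or HG+CD200Fc replicate 2 (0.12), and cytokines without each library except HG replicate 3 and HG+CD200Fc replicate 2 (-0.18 without NG+CD200Fc replicate 1 to -0.087 without HG+CD200Fc replicate 1).

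In HG+CD200Fc vs NG+CD200Fc the mitochondrially encoded (median -0.039), cytokine (-0.031), NF-kB (0.065) and G2 and M phase (-0.036) lists lost their calls with the exon length and GC trend removed. Upper quartile scaling ended the calls of the citrate cycle, cholesterol synthesis and G2 and M phase lists. Log2 fold changes in this comparison rose with exon length (Spearman rho = 0.242) and GC content (0.241) across genes. The median, mean or test differed in sign for the fatty acid, cholesterol efflux, homeostatic microglia, alternative activation, heat shock, angiogenic, migration, astrocyte and oligodendrocyte lists, none of which passed. The largest single changes were less stable. *Ovol1* (1.83 ± 0.42) lost its call with DESeq2 and without NG+CD200Fc replicate 3 or HG+CD200Fc replicate 3 (range 1.19 to 2.17 over the alternatives). *Lrp2* (-1.20 ± 0.33) lost its call with DESeq2 and without NG+CD200Fc replicate 1 or 3 or HG+CD200Fc replicate 1 or 2 (range -1.56 to -1.002).

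Whether CD200Fc acted differently at the 2 glucose levels was tested with the interaction, the CD200Fc effect in high glucose minus that in normal glucose. In all 1381 genes passed (edgeR), 694 with a positive and 687 with a negative interaction, and at least 2-fold 23 and 155. The positive share was 50.3%, and 45.9% without HG+CD200Fc replicate 2 to 58.0% without HG replicate 1. Of the lists with a negative median, interferon-stimulated genes had the smallest adjusted p (35 of 45, 39 adjusted over the list alone; median -0.85, adjusted p = 8.81e-67). Members included *Irf7* (-1.12 ± 0.090), *Oasl2* (-1.37 ± 0.11) and *Ifit2* (-1.70 ± 0.16). Antigen presentation (12 of 24, 16 adjusted over the list alone; median -0.49, adjusted p = 1.67e-17) and complement genes (10 of 17, 12 adjusted over the list alone; median -0.64, adjusted p = 4.47e-13) followed. Ribosome biogenesis and MYC targets were positive (19 of 34, 27 adjusted over the list alone; median 0.31, adjusted p = 2.12e-20). Examples are *Srm* (0.54 ± 0.078) and *Cad* (0.60 ± 0.086). These 4 of the 24 lists that passed kept their calls with an estimated correlation. *Txnip* (-0.52 ± 0.087, adjusted p = 2.90e-04) and *Malat1* (-0.57 ± 0.080) were among the single genes that passed. In the interaction of glucose and CD200Fc the ribosomal protein list did not pass (median -0.025, adjusted p = 0.931), but passed with a positive median without HG replicate 1 (0.090) or NG+CD200Fc replicate 3 (0.073). It passed with a negative median without HG replicate 2 (-0.092). The median, mean or test differed in sign for the CD200 signalling, p53, ribosomal protein, angiogenic, migration, nuclear RNA and oligodendrocyte lists, none of which passed.

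Across all 19182 genes (which are not independent replicates) the CD200Fc effects at the 2 glucose levels had a Pearson r of 0.0283 and a Spearman rho of 0.0671, with a two-sided permutation p = 0.57 over 400 relabellings of libraries (adjusted p = 0.57 over 2 relations). The glucose effects without and with CD200Fc had r = 0.278 and rho = 0.342, with a permutation p = 0.02 and adjusted p = 0.04, the smallest p possible being 0.01. Neither pair of comparisons shares a library. Log2 fold changes rose with exon length in each of these comparisons (Spearman rho = 0.151 to 0.276), and a shared trend can raise such correlations. Neither the correlations nor the shared calls below were computed with the trend removed. The 2244 genes higher in HG had a median log2 fold change of 0.52 without CD200Fc and 0.13 with it, and the 2476 lower genes medians of -0.32 and -0.12. These genes were chosen by the first of the 2 values, which choice enlarges, so a smaller second median does not by itself show a smaller effect. With CD200Fc 342 of the higher genes and 355 of the lower genes passed again in the same direction, against 104 and 90.5 for independent lists, and 28 and 33 passed in the other direction.

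**Figure D3:**
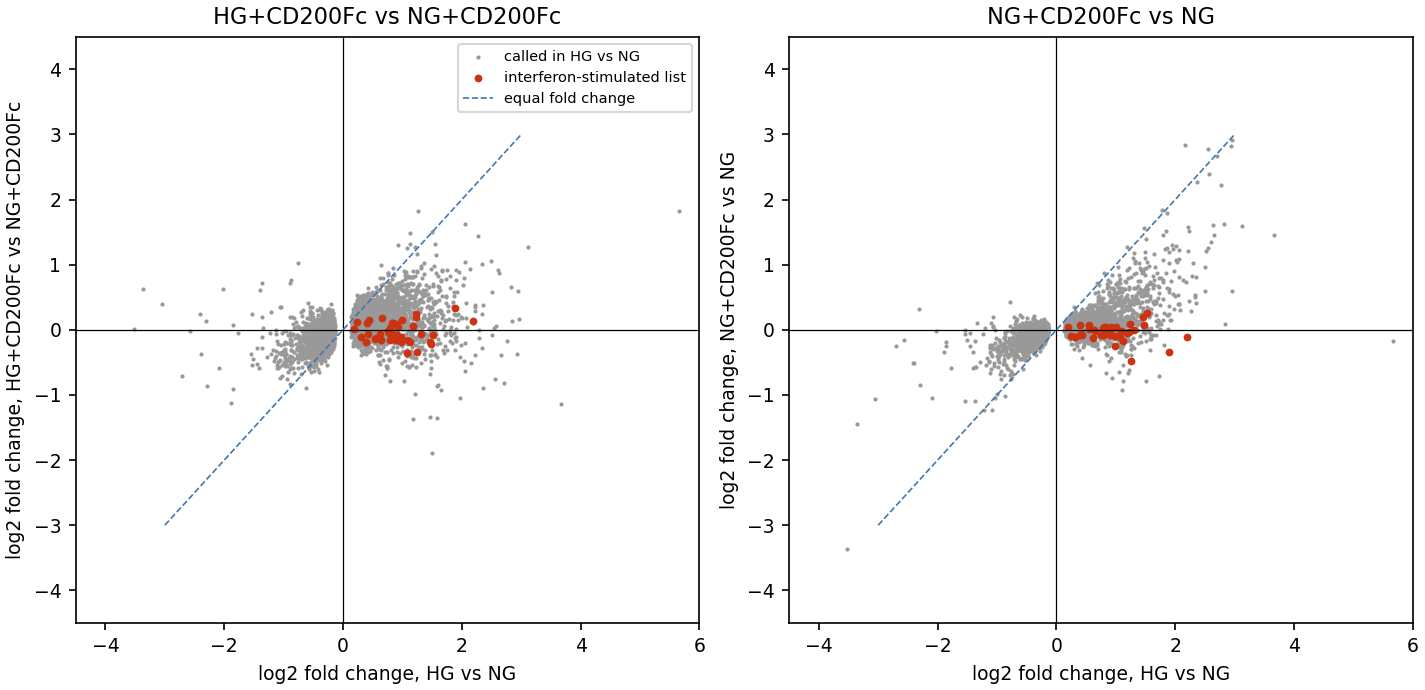
Log2 fold changes of the 4720 genes that passed in HG against NG (x axis), against their log2 fold changes in HG+CD200Fc against NG+CD200Fc (left) and in NG+CD200Fc against NG (right), 1 point per gene, interferon-stimulated genes in red, dashed line at equal change. Over all its tested genes, including those not drawn, the interferon-stimulated list has medians of -0.058 (left comparison) and -0.019 (right comparison). The right panel shares the NG libraries between its axes.

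Genes that passed in HG vs NG were set against those that passed in HG+CD200Fc vs HG. In all 1781 genes passed in both with opposite signs: 928 were higher in HG and lower with CD200Fc, against 186 for independent lists, and 853 were lower and then higher, against 234. Only 67 passed in both with the same sign. The comparisons share the 3 HG libraries, which alone push their fold changes apart. In 40 simulations of unchanged groups a mean of 0.05 and at most 1 gene passed in opposite directions. Almost no gene can pass in such simulations. They therefore cannot show how many opposite calls the shared libraries add where many genes pass. The mean simulated correlation was -0.488 against an observed -0.532. The covariance was -0.101 against a simulated -0.0397, a difference of -0.0615. The 3 HG libraries are too few to be split, so part of the excess may come from them.

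The authors' deposited table of comparisons was matched on 14897 genes. The authors' deposited table had 4883 genes past its threshold in HG against NG (2440 higher and 2443 lower), 3475 in HG+CD200Fc against HG (1770 and 1705), 0 in NG+CD200Fc against NG (smallest FDR 0.0751) and 3995 in HG+CD200Fc against NG. The edgeR test, run also on HG+CD200Fc against NG for this purpose alone, called 4720, 3408, 0 and 3903 of 19182 genes. Of the matched genes, those under the limit both in the authors' deposited table and here numbered 4378, 3161, 0 and 3619, with 0 differences in sign.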

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

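The tests of single libraries, of culture density and of the histones with the trend removed in this part were chosen only after the results were seen. What was singled out here is a difference between the CD200Fc effects in high and in normal glucose, by the interaction test of edgeR or, for lists, of camera. It covers 1381 genes and 24 of the 44 lists tested, of which the interferon-stimulated, antigen presentation, complement and ribosome biogenesis lists kept their calls with an estimated correlation.

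A negative interaction (log2) means that the log2 fold change with CD200Fc was more negative, or less positive, in high than in normal glucose. Negative medians were found for interferon-stimulated genes (-0.85), complement (-0.64), antigen presentation (-0.49), Fc receptors (-0.35), glucose-sensing targets (-0.25), inflammatory cytokines (-0.24), hypoxia and HIF1 (-0.22), pattern receptors (-0.22), glycolysis and lactate (-0.21), inflammatory enzymes (-0.18), alternative activation (-0.17), cholesterol efflux (-0.15), disease-associated microglia (-0.15), NF-kB (-0.14) and phagocytosis and lysosome (-0.072). The lymphocyte marker list had -1.30, from 6 tested genes of which *Cd4* alone passed. Positive medians were found for replication-dependent histones (0.45), ribosome biogenesis (0.31), S phase (0.22), G2 and M phase (0.20), osmotic stress (0.17), immediate early genes (0.15), the integrated stress response (0.13) and heat shock (0.13).

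In the interaction of glucose and CD200Fc 5 lists lost their calls when single libraries were left out. Immediate early genes lost theirs without NG replicate 1 (median 0.080), NG+CD200Fc replicate 3 (0.079), HG replicate 2 (0.11) or HG+CD200Fc replicate 2 (0.080). Disease-associated microglia genes lost theirs without NG replicate 2 (-0.11), NG+CD200Fc replicate 3 (-0.081), HG replicate 1 (-0.074) or HG+CD200Fc replicate 3 (-0.13), and phagocytosis genes without NG replicate 2 (-0.054), NG+CD200Fc replicate 3 (-0.039) or HG replicate 1 (-0.027). Alternative activation lost its call without NG replicate 2 (-0.14) or 3 (-0.14), NG+CD200Fc replicate 1 (-0.084), HG replicate 3 (-0.11) or HG+CD200Fc replicate 2 (-0.16) or 3 (-0.11), and lymphocyte markers without HG replicate 3 (-0.92).

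Genes with a negative interaction (log2) were *Il1a* (-2.93), *Ankrd37* (-2.43), *Apol9a* (-2.39), *Cd4* (-2.06), *Gbp4* (-2.04), *Pirb* (-1.91), *Ifit2* (-1.70), *Slc16a3* (-1.57), *Ndrg1* (-1.46), *C1qb* (-1.38), *Oasl2* (-1.37), *Mmp9* (-1.14), *Irf7* (-1.12), *Nos2* (-0.93), *Tap1* (-0.92), *Cd74* (-0.84), *C3* (-0.64), *Malat1* (-0.57) and *Txnip* (-0.52). Genes with a positive interaction were *Dmpk* (2.64), *Cx3cr1* (2.08), *Pmepa1* (1.93), *Kcna3* (1.78), *Epha2* (1.49), *Etv4* (1.18), *Cad* (0.60), *Srm* (0.54) and *Plk1* (0.54). *Il1a* and *Cd4* did not pass with DESeq2, and *Il1a* moved to -4.03 without HG+CD200Fc replicate 1. *Pmepa1* lost its call without NG replicate 1 or 2, NG+CD200Fc replicate 1, HG replicate 1 or 3 or HG+CD200Fc replicate 1, with a range of 1.67 to 2.53 over the alternatives.

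The first pattern weighed is the higher expression of interferon, antigen presentation and complement genes in HG and not in HG+CD200Fc. For the interferon-stimulated list a single library was argued against: over the leave-outs its lowest median log2 fold change in HG vs NG was 0.78. For the same list the scaling of the libraries or a trend with exon length and GC content was argued against too. Its lowest median over the other scalings and the trend removal was 0.82. The antigen presentation and complement lists were not weighed in these ways. Denser or nutrient-poor HG cultures stay open: the G2 and M phase list had a median of -0.28, which such cultures could also give, and no culture density is recorded. A higher share of nuclear RNA in the HG libraries stays open too: *Malat1* had a log2 fold change of 0.83 in HG vs NG and -0.57 in HG+CD200Fc vs HG. *Neat1* was also higher in HG vs NG (0.51), with its call lost in 5 of 21 alternatives. Genes of unconfirmed (TEC) or sense-intronic biotype held 0.269% of the counts in NG, 0.365% in HG and 0.341% in HG+CD200Fc (means). Other nuclear RNA went the other way: *Rn7sk* held 0.410% of the counts in NG and 0.255% in HG (means), and small nuclear and nucleolar RNA 0.0612% and 0.0499%. The list of nuclear noncoding RNA and RNA quality genes passed in neither HG vs NG nor HG+CD200Fc vs HG (medians -0.35 and -0.13). High glucose itself, its osmolarity and the Fc part of CD200Fc also stay open, since the groups hold no control for them. A response to glucose that CD200Fc lowers is therefore a hypothesis only.

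The second pattern is the lower expression of ribosomal protein, oxidative phosphorylation and histone genes in HG. For the ribosomal protein list a single library was argued against, with a highest median of -0.19 over the leave-outs in HG vs NG. The oxidative phosphorylation and histone lists were not weighed in this way. The mean of the ribosomal protein list against NG ran from -0.405 to -0.080 in the HG libraries. The highest of these lay within the range of the NG libraries, -0.093 to 0.116. In the NG+CD200Fc libraries the mean of this list ran from -0.249 to -0.028, overlapping HG, so lower ribosomal protein values were not particular to HG. The oxidative phosphorylation and histone lists averaged -0.168 and -0.286 in NG+CD200Fc, against -0.278 and -0.870 in HG. Each value is set against the same NG libraries, so chance in those moves HG and NG+CD200Fc the same way. For the ribosomal protein and oxidative phosphorylation lists, a bias with exon length and GC content cannot be told apart from a change in these genes. Genes matched to the ribosomal protein list on exon length, GC and level, 229 in number, had a median of -0.21 (SD 0.27) against -0.27 for the list, a ratio of 0.772, while the list kept 0.778 of its median once the trend was removed. The matching was imperfect, with a median exon length of 2385 against 1770 bases. Matched genes had -0.19 against -0.27 for oxidative phosphorylation, where 0.728 of the median was kept. For histones the bias as the whole cause was argued against: with the trend removed their median was -0.75 of -0.88 and still passed, against -0.26 (SD 0.37) for matched genes, which were longer (median 1139.5 against 715.5 bases). The histone list did not pass with an estimated correlation (camera adjusted p = 0.166). No biological explanation was tested for this pattern.

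Other splits of the same libraries were counted for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In HG vs NG the real split called 4720 genes and the highest other split 0 (1 of the splits as large), in HG+CD200Fc vs HG 3408 and 2 (1 as large), in HG+CD200Fc vs NG+CD200Fc 1593 and 2 (1 as large), and in NG+CD200Fc vs NG 0 and 0 (10 as large). For the interaction 4 of 100 splits called at least the 1381 genes of the real one, and the highest other split called 2382. The outcome followed from whether a split left the HG and HG+CD200Fc libraries as labelled: 5 others that did called 1018 to 2382 genes, while splits that mixed them called at most 4. Of the 6 with these libraries as labelled, the real one included, 4 called at least 1381, so chance in the grouping of the NG and NG+CD200Fc libraries is not excluded.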

How the results depend on the processing

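The alternative that removed the exon length and GC trend was chosen only after the data were seen. Over 510 results and their alternatives, 10380 values were counted as the same, 343 as weaker, 73 as stronger, 21 as moved and 1 as reversed. A count was the same within 1.5 times, and a correlation within the SD of its permuted values. A gene or list that passed in neither setting was also counted as the same, whatever its sign, so the same does not mean that the direction was kept. The reversed one is the direction of camera for the ribosomal protein list in the interaction, higher and not passing with all libraries (median -0.025) and lower and passing without HG replicate 2 (median -0.092). The median ranged from -0.092 to 0.090 over the leave-outs, and was positive and passing without HG replicate 1 (0.090) or NG+CD200Fc replicate 3 (0.073).

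The counts of genes passing in HG vs NG (3326 to 5045 over the leave-outs), HG+CD200Fc vs HG (2473 to 3568) and the interaction (974 to 1505) stayed within 1.5 times in each alternative run. So did the count of opposite calls (1428 to 1889 over the leave-outs), run only with DESeq2 size factors, the other filters, the replicate block and the leave-outs. The correlation of the CD200Fc effects ranged from -0.018 to 0.071 over the leave-outs. In HG+CD200Fc vs NG+CD200Fc, 1593 genes became 2559 with limma voom, 1012 with the trend removed, and 277 to 2288 over the leave-outs. In NG+CD200Fc vs NG, 0 became 21 with no filter, 9 with only the groups compared, 2 with the replicate block and 0 to 8 over the leave-outs.

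With an estimated correlation the lists passing were 8 of 23 in HG vs NG, 0 of 16 in HG+CD200Fc vs NG+CD200Fc, 0 of 5 in NG+CD200Fc vs NG, 7 of 23 in HG+CD200Fc vs HG and 4 of 24 in the interaction. This correlation was larger than the preset one for most lists. How far its size accounts for the lost calls was not tested. With fry 4 lists passed in HG+CD200Fc vs NG+CD200Fc and 0 in NG+CD200Fc vs NG. Over the leave-outs lists passing ranged from 21 to 23, 12 to 16, 3 to 9, 20 to 24 and 21 to 25 in the same order. The correlation of the glucose effects, 0.278, was 0.150 with no filter, 0.383 with the stricter filter and 0.211 to 0.286 over the leave-outs. Apart from the smaller groups of the leave-outs and the genes added or removed by the filters, the cause was not tested.

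Labels number the replicates, but a model without pairing was planned beforehand. Residuals of same-numbered libraries had correlations of -0.158 to 0.367 (mean 0.0809, against -0.0406 for other numbers), so pairing is not excluded. With the replicate number as a block, 5258 genes passed in HG vs NG and 3842 in HG+CD200Fc vs HG. In HG+CD200Fc vs NG+CD200Fc 2314 passed, and in the interaction 1723. At this depth, 1.5-fold changes in simulated data were recovered in 61.2% of genes in HG vs NG and 43.3% in the interaction, so smaller changes can be missed. Only genes with a mean of at least 1 CPM were changed in these data.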

Other observations

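This part reports no test, and its values were looked at after the results were seen. HG replicate 2 had 1.49% of its counts in ribosomal RNA genes, and *Mir6236* stood at 1252 CPM (before TMM scaling) in it against 16.9 and 24.8 in the other HG libraries. A single gene took 2.83% to 4.96% of the counts of each library. *Ifnb1* had 32 reads in all libraries together and was not tested.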
